A study of Oryza sativa with 10 samples.

How the data were processed

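Rice calli, undifferentiated tissue grown on agar in the dark at 23 ± 2 °C with the auxin 2,4-D, were 17 days old and had spent about 324 h in their condition when total RNA was taken. RNA from 10 samples was amplified and biotin-labelled with a kit that primes at the 3' end and hybridised to Affymetrix rice arrays, per the labels. The groups, taken from the sample titles, were spaceflight (4 arrays), a 1g control kept in flight (3 arrays) and a 1g control kept on the ground (3 arrays). The treatment text in the labels is the same for every sample, so the titles alone define the groups. These titles call all 3 groups a control, spaceflight included, and no label names a group as treated, so its reading as the microgravity group rests on the word spaceflight. The labels call the replicates biological and do not say what was separate between them.

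The deposited values are log2 MAS5 signals of probe sets, with MAS5 named without a version in the submitters' processing notes. On the linear scale the trimmed mean of every array was 500.1, so the authors had scaled the arrays to one target. No value lies below 0, and 733 to 1196 probe sets per array are listed at 0. The median log2 value per array ran from 5.34 to 5.64. The chip description file, background settings and detection calls are not given in the sources used here, so signal over background is unknown per probe set and the number of arrays limits the precision.

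The table holds 57381 probe sets, of which 123 are Affymetrix controls and 57258 are not. The probe table gave 1 gene for 22436 probe sets, several for 95 and none for 34727. All 22436 were matched by gene number to a RefSeq gene table of rice (assembly ASM3414082v1, used for names only), giving 17905 genes, of which 2457 had a name beyond a locus number. A gene was represented by the probe set with the highest mean, and a probe set with several genes was left out. No coordinates are given, because no build is stated.

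Values were used as deposited, with no pseudocount and no further normalization. Probe sets other than controls whose mean log2 value over the 10 arrays was in the upper 60% were kept, which left 34355 with a mean of at least 4.17. limma 3.58.1 in R 4.3.3 fitted all 10 arrays with 3 groups (lmFit and eBayes), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Differences are on the log2 scale with the standard error (SE) of the moderated fit. Figures were drawn with matplotlib 3.10.9, and tables were joined with pandas 2.3.3 in Python 3.11.15.

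Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Of the 33 lists fixed before the data were examined, 17 had at least 5 measured genes and were tested. The lists match words in symbols and synonyms, and known false matches were left in: an acireductone dioxygenase gene among the heat shock genes, the small GTPase RAB5A among the abscisic acid genes, a histone among the meristem genes, a bHLH factor among the aquaporins, and the defence regulator NH1 among the pathogenesis-related proteins. Because so few planned lists could be tested, 25 lists based on symbols were written after the gene names had been seen and before any gene was tested. They were adjusted as a family of their own.

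The named genes followed a rule fixed before the data were examined. For each comparison it took the 8 largest rises and 8 largest falls among genes past the threshold whose groups did not overlap. It then took up to 2 risen and 2 fallen genes from each shifted list and from the 4 lists with most changed genes. A symbol was read as a name other than a locus or clone number. Genes from the symbol lists were picked by the same steps but lie outside that rule and were chosen afterwards.

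The fit was tested on simulated data with 200 changed probe sets among 34355, at log2 sizes of 1 and 2. For spaceflight against inflight 1g it recovered 23% and 40%, with 1 false call. For spaceflight against ground 1g it recovered 29% and 43%, with 4 false calls, and for inflight 1g against ground 1g 21% and 41%, with 7 false calls. The real comparisons called 5999, 4211 and 1367 probe sets in the same order, far more than the 200 changed here. Recovery after Benjamini-Hochberg adjustment depends on the share changed. These rates therefore hold for the simulated share only and do not estimate what the real comparisons missed. RNA quality was followed as the mean log2 ratio of 3' to 5' signal over 5 control pairs, with exact two-sided permutation tests between groups. The alternatives tried before seeing the data covered the pseudocount, the filter, quantile normalization, median centring, the replicate number as a block, the arrays in the fit, the variance model, array weights, a 2-fold threshold, the correlation in camera, the probe set of a gene and each array left out. A fit with the 3' to 5' ratio as a covariate and fits without a pair of spaceflight arrays were added after the control probe sets had been seen. A fit with the mean log2 signal of 5 rRNA control probe sets as a covariate and a split of the ground arrays were added after the gene results had been seen.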

Results

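Transcript levels were measured on 10 arrays of rice callus, with 4 arrays from spaceflight, 3 from a 1g control kept in flight and 3 from a 1g control kept on the ground. The series set out to find genes that change in microgravity. Spaceflight against inflight 1g holds flight constant, spaceflight against ground 1g differs in both gravity and flight, and inflight 1g against ground 1g compares flight at the same gravity. After filtering, 34355 probe sets were tested, and 15888 genes were represented among them.

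The lipid transfer protein gene LTP-2, the embryo gene EM and the dehydrin gene RAB21 were higher in spaceflight than in inflight 1g. LTP-2 (LOC4331362) had a log2 signal of 12.53 ± 1.23 (SD, n = 4) in spaceflight and 5.34 ± 0.67 (SD, n = 3) in inflight 1g, a difference of 7.18 (SE 0.78, limma adjusted p = 0.00279). EM (LOC4338499) rose by 6.43 (SE 0.91) and RAB21 (LOC4350454) by 6.43 (SE 0.72). The late embryogenesis gene LEA19 rose by 5.14 (SE 0.54) and the dehydrin gene RAB16B by 3.79 (SE 0.38). Another dehydrin gene, LIP9 (LOC4330265), chosen after its value was seen, differed by -0.36 (SE 0.29, limma adjusted p = 0.42). TIP3-1, an aquaporin of the vacuole membrane, rose by 4.26 (SE 0.56), the ethylene receptor gene ETR4 by 4.10 (SE 0.78), the protein phosphatase gene OsPP2C59 by 5.40 (SE 0.87) and the oxophytodienoate reductase family gene OPR12 by 4.68 (SE 0.64). The inflight means of OsPP2C59 and OPR12, 2.82 and 1.76, lay below the filter level of 4.17, so their differences rest on dim signals. All these differences are against inflight 1g. Against ground 1g EM, RAB21 and RAB16B missed the threshold, at 2.92, 1.58 and 1.20 (limma adjusted p = 0.0694, 0.183 and 0.0723). LEA19 passed it there at 2.26 (limma adjusted p = 0.0316), and LTP-2 is given below.

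**Figure D1:**
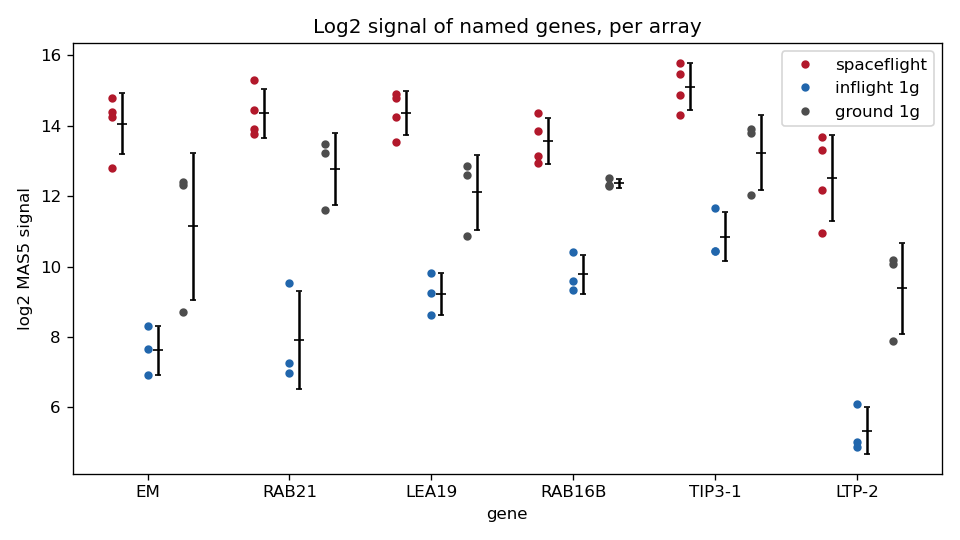
Log2 MAS5 signal per array (vertical axis) of 6 genes (horizontal axis), with points for arrays and black marks for the group mean ± SD in spaceflight (n = 4), inflight 1g (n = 3) and ground 1g (n = 3). RAB21 had a mean of 14.36 in spaceflight, 12.78 in ground 1g and 7.93 in inflight 1g.

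A chitinase gene (LOC4351188) fell from 12.92 ± 0.35 (SD, n = 3) in inflight 1g to 6.89 ± 1.24 (SD, n = 4) in spaceflight, and the related Chib3H-h fell by 4.92 (SE 0.93). The cell wall invertase gene CIN1 fell by 5.39 (SE 0.82), to a dim spaceflight mean of 3.51. LPR1 fell by 4.86 (SE 1.00), to a dim mean of 4.05, and TPP1, a trehalose phosphate phosphatase gene, fell by 4.34 (SE 0.79). CYP701A8, a cytochrome P450 of diterpene metabolism, fell by 3.68 (SE 1.00), GLU6 fell by 3.55 (SE 0.40) and the cinnamyl alcohol dehydrogenase gene CAD7 fell by 3.33 (SE 0.81). Against ground 1g CYP701A8 differed by 0.09 (SE 1.00, limma adjusted p = 0.965), while LOC4351188, CIN1 and TPP1 were lower there too.

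Of the 17 planned lists, 2 were shifted in this comparison, and 0 without spaceflight replicate 3 or without replicates 3 and 4. The abscisic acid list was also lost with no filter (adjusted p = 0.0558) and with the signal of rRNA control probe sets as a covariate (adjusted p = 0.062), and the WRKY list with median centring (adjusted p = 0.0979). The abscisic acid and dehydration list was higher (camera adjusted p = 0.0319, and adjusted p = 0.491 with an estimated correlation), with 4 of its 5 genes higher and 1 lower, and the same counts adjusted over the list alone. The 1 lower gene was RAB5A, a small GTPase of vesicle transport. Between spaceflight and ground 1g this list was not shifted (camera adjusted p = 0.35), with 1 of 5 genes higher. WRKY factors, regulators of stress and defence, were lower (adjusted p = 0.0319, and adjusted p = 0.316 with an estimated correlation), with 2 of 6 lower, and 3 lower adjusted over the list alone. WRKY71 fell by 1.28 (SE 0.16) and WRKY51 fell by 0.85 (SE 0.19). The WRKY list was not shifted between spaceflight and ground 1g either (camera adjusted p = 0.579), where WRKY71 differed by 0.00 (SE 0.16). The aquaporin and ion transporter list missed the threshold (adjusted p = 0.0672), with 8 of 34 higher and 1 lower, and 10 higher and 2 lower adjusted over the list alone. In it PIP2-8 rose by 1.17 (SE 0.21) and the potassium transporter gene HAK1 fell by 0.97 (SE 0.25).

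Meristem regulators missed the threshold (camera adjusted p = 0.078), with 2 of 9 lower, and 3 lower adjusted over the list alone. Pathogenesis-related proteins missed it as well (adjusted p = 0.078), with 1 of 6 higher and 2 lower, and 4 lower adjusted over the list alone. Among 47 calcium signalling genes 5 were higher and 5 lower, and the same numbers passed adjusted over the list alone. The kinase genes CPK21 and CPK18 rose by 1.17 (SE 0.20) and 1.09 (SE 0.22), while CPK12 fell by 3.01 (SE 0.49) and CPK7 fell by 1.84 (SE 0.30). Of 40 heat shock genes 5 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.561). HSFA6B rose by 2.88 (SE 0.34) and HSP18.0 by 0.85 (SE 0.20), and HSFA4D fell by 2.33 (SE 0.42). The list's other fall was an acireductone dioxygenase gene, ARD1, at -0.77 (SE 0.16), which had 1 spaceflight array apart from the other 3. Of 52 auxin response genes 9 were higher and 5 lower, and 9 higher and 7 lower adjusted over the list alone. ARF24 rose by 1.38 (SE 0.16) and IAA8 by 3.64 (SE 0.58), the latter from a dim inflight mean of 2.27, while IAA9 fell by 1.60 (SE 0.22) and IAA20 fell by 2.04 (SE 0.32).

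In lists written from symbols, genes of protein folding in the endoplasmic reticulum were lower (adjusted p = 0.00498, and adjusted p = 0.397 with an estimated correlation), with 1 of 31 higher and 6 lower, and 1 higher and 8 lower adjusted over the list alone. The chaperone gene ERDJ3B fell by 1.05 (SE 0.14), and the 1 risen gene was PDIL1-2 at 1.08 (SE 0.26). Diterpenoid phytoalexin genes, which make antimicrobial compounds, were also lower (adjusted p = 0.0277, and adjusted p = 0.528 with an estimated correlation), with 2 of 11 lower, also adjusted over the list alone. The terpene synthase gene KSL7 fell by 2.94 (SE 0.66). Between spaceflight and ground 1g the diterpenoid list was not shifted (camera adjusted p = 0.802). The diterpenoid call was kept in 16 of 25 settings, and it was lost with no filter (adjusted p = 0.0769), the upper 40% filter (adjusted p = 0.0746), median centring (adjusted p = 0.19) and array weights (adjusted p = 0.0711). It was also lost without inflight 1g replicate 1 (adjusted p = 0.103) or 3 (adjusted p = 0.0572), and without spaceflight replicates 1 and 2 (adjusted p = 0.0813) or 3 and 4 (adjusted p = 0.0679).

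In all, 5999 probe sets differed between spaceflight and inflight 1g (limma with Benjamini-Hochberg adjustment), 3942 higher and 2057 lower, and 3554 of them by at least 2-fold. The groups did not overlap for 30.04% of probe sets, where chance gives 5.71%. The share of higher calls was 65.7% as deposited, 54.7% after quantile normalization and 34.8% after median centring, which moved the median of all probe sets from 0.10 to -0.15, so the balance of rises and falls depends on the scaling. The count was 3599 without spaceflight replicate 1, 3080 without inflight 1g replicate 1, 3956 without inflight 1g replicate 2, 3203 with only these 2 groups in the fit, 2877 with no filter, and 2558 without spaceflight replicates 1 and 2, whose BioB spike-in was brighter by 3.49 on the log2 scale than that of the other 8 arrays.

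In spaceflight against ground 1g, the chalcone isomerase gene CHI, of flavonoid synthesis, rose by 4.36 (SE 0.89) from a dim ground mean of 2.62, and the zinc transporter gene ZIP5 rose from 5.99 ± 1.65 (SD, n = 3) to 9.90 ± 0.56 (SD, n = 4). PM19L rose by 3.19 (SE 0.51), LTP-2 by 3.14 (SE 0.78), the phosphatase gene PP2C30 by 3.05 (SE 0.50) and the aquaporin gene TIP3-2 by 2.90 (SE 0.70). The sugar transporter gene SWEET1A rose by 2.59 (SE 0.56) from a dim ground mean of 3.44, and the calcium pump gene ACA5 by 2.45 (SE 0.31). The chitinase gene LOC4351188 fell by 4.68 (SE 0.65, limma adjusted p = 0.00779) and the chitinase gene Cht5 fell by 4.23 (SE 0.77). The transcription factor gene BZIP52 fell by 4.19 (SE 0.54), the hexokinase gene HXK6 fell by 4.15 (SE 0.68) and TPP1 fell by 3.96 (SE 0.79). The germin-like gene GER6 fell by 3.88 (SE 0.98), CIN1 fell by 3.58 (SE 0.82) to its dim spaceflight mean, and the auxin carrier gene PIN2 fell by 3.04 (SE 0.59).

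The 3' to 5' signal ratio of control probe sets, a sign of RNA quality, also differed from ground, at 2.45 ± 0.23 (SD, n = 4) in spaceflight, 2.35 ± 0.17 (SD, n = 3) in inflight 1g and 1.86 ± 0.09 (SD, n = 3) in ground 1g on the log2 scale. Exact two-sided permutation tests gave p = 0.0571 for spaceflight against ground 1g, p = 0.1 for inflight 1g against ground 1g and p = 0.343 for spaceflight against inflight 1g. These p-values double the smaller tail. In this form the first is the smallest possible for 4 against 3 arrays and the second for 3 against 3. None of these tests could therefore pass 0.05 as computed, and for 4 against 3 arrays this limit comes from the doubling. With middle in place of 5' probe sets the differences from ground 1g were 0.26 for spaceflight and 0.27 for inflight 1g, in place of 0.59 and 0.49. The rRNA control probe sets had lower means in flight, at 11.54 ± 0.65 (SD, n = 4) in spaceflight, 12.48 ± 0.85 (SD, n = 3) in inflight 1g and 13.34 ± 0.48 (SD, n = 3) in ground 1g, and within spaceflight they were lowest in replicates 1 and 2. The same exact tests gave p = 0.171 for spaceflight against inflight 1g, p = 0.0571 for spaceflight against ground 1g and p = 0.2 for inflight 1g against ground 1g.

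**Figure D2:**
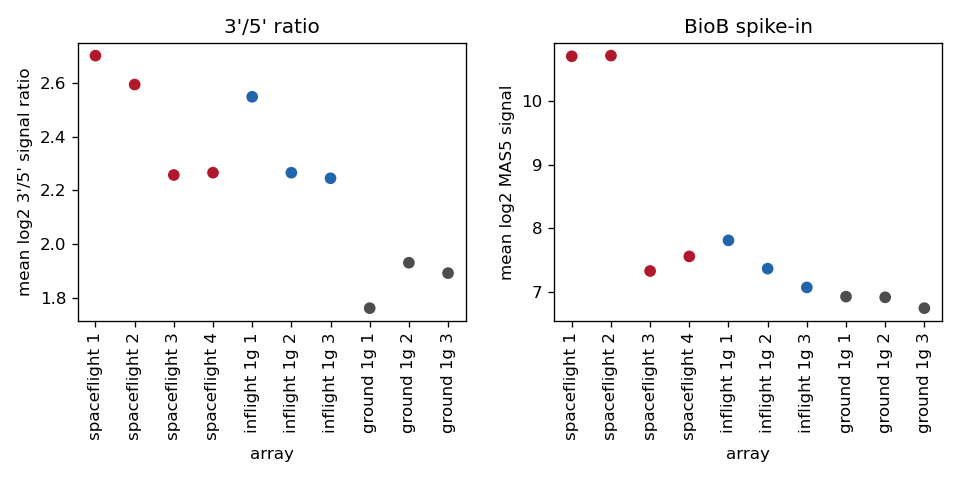
Mean log2 3' to 5' signal ratio of control probe sets (left) and mean log2 signal of the BioB spike-in (right) for each of the 10 arrays, one point per array. The ground ratios lay between 1.76 and 1.93 and those of the flight arrays between 2.24 and 2.70, and BioB was 10.7 in spaceflight replicates 1 and 2.

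Of the planned lists, 3 were shifted between spaceflight and ground 1g, and 0 with the 3' to 5' ratio or the rRNA signal as a covariate. The cell cycle list was also lost without spaceflight replicates 1 and 2 (adjusted p = 0.0699) or ground 1g replicate 1 (adjusted p = 0.0505). The pathogenesis list was lost with median centring (adjusted p = 0.0655) and without spaceflight replicate 3 (adjusted p = 0.0563) or ground 1g replicate 3 (adjusted p = 0.0781). Aquaporins and ion transporters were higher (camera adjusted p = 0.000954, and adjusted p = 0.427 with an estimated correlation), with 7 of 34 higher and 0 lower, and 10 higher adjusted over the list alone. HAK1 rose by 1.60 (SE 0.25) and HAK18 by 1.00 (SE 0.19). Cell cycle and replication genes were lower (adjusted p = 0.0291, and adjusted p = 0.797 with an estimated correlation), with 6 of 22 lower and 0 higher, and 8 lower and 2 higher adjusted over the list alone. The replication gene PCNA fell by 1.09 (SE 0.15) and MCM4 fell by 1.43 (SE 0.22). Pathogenesis-related proteins were lower (adjusted p = 0.0293, and adjusted p = 0.427 with an estimated correlation), with the chitinase genes LOC4351188 and Cht5 lower among 6, also adjusted over the list alone. Besides NH1, every measured gene of this list carries the name chitinase, so it does not stand for other pathogenesis-related proteins.

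Of 52 auxin response genes 5 were higher and 7 lower against ground 1g, and 8 higher and 7 lower adjusted over the list alone. ARF16 was 2.84-fold higher and ARF7 rose by 0.93 (SE 0.14), while IAA20 fell by 2.87 (SE 0.32) and GH3.2 fell by 1.41 (SE 0.16). Of 47 calcium signalling genes 1 was higher, the kinase gene CIPK32 by 0.75 (SE 0.12), and 3 were lower, and 5 were higher and 4 lower adjusted over the list alone. CPK1 fell by 0.53 (SE 0.12) and the calcium sensor gene CBL2 fell by 0.73 (SE 0.17). Among symbol lists, cyclins and replication genes were lower (adjusted p = 0.000116, and adjusted p = 0.496 with an estimated correlation), with 2 of 65 higher and 17 lower, and 3 higher and 20 lower adjusted over the list alone. The cyclin gene CYCD5-1 was one that rose, by 2.24 (SE 0.55). PCNA belongs to this list and to the planned cell cycle list, so the 2 calls are not separate support. Ribosomal proteins were lower (adjusted p = 0.000116, and adjusted p = 0.446 with an estimated correlation), with 5 of 25 lower and 6 adjusted over the list alone, such as RPS26 at -0.77 (SE 0.12). Endoplasmic reticulum folding genes were lower (adjusted p = 0.00436, and adjusted p = 0.318 with an estimated correlation), with 7 of 31 lower and 8 adjusted over the list alone. Protein phosphatases 2C were higher (adjusted p = 0.0202, and adjusted p = 0.229 with an estimated correlation), with 9 of 54 higher and 1 lower, and 13 higher and 1 lower adjusted over the list alone. OsPP2C16 rose by 1.28 (SE 0.19) and OsPP2C34 fell by 0.67 (SE 0.15). The calls of cyclins and of protein phosphatases 2C were lost with the 3' to 5' ratio as a covariate (adjusted p = 0.612 and 0.224) and with the rRNA signal (adjusted p = 0.264 and 0.105). The phosphatase call was also lost with the upper 40% filter (adjusted p = 0.0537), without spaceflight replicates 1 and 2 (adjusted p = 0.0615) and without ground 1g replicate 2 (adjusted p = 0.0622).

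Between spaceflight and ground 1g 4211 probe sets differed (limma with Benjamini-Hochberg adjustment), 2404 higher and 1807 lower, and 2056 by at least 2-fold. The groups did not overlap for 31.6% of probe sets, where chance gives 5.71%. The share of higher calls was 57.1% as deposited and 42.6% after median centring, and the count was 431 with the 3' to 5' ratio as a covariate, 1 with the rRNA signal as a covariate, 2586 without spaceflight replicates 1 and 2, and 1017 with no filter. It was 2084 and 2749 without spaceflight replicates 1 and 2 in turn, and 1389, 1903 and 697 without ground 1g replicates 1, 2 and 3 in turn. Over the 4211 probe sets the median size of the difference was 0.98, and 0.89 and 0.93 with the ratio and the rRNA covariate, while the median SE was 0.20, and 0.35 and 0.32 with them.

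Both spaceflight comparisons called 2068 probe sets in the same direction, 1495 higher and 573 lower, and 33 in opposite directions. Independent lists would share 275.8 higher and 108.2 lower, and simulated unchanged groups sharing the spaceflight arrays made 0 calls, so they gave no value for this overlap. The differences correlated across probe sets at r = 0.60 against 0.44 simulated, with a covariance of 0.48 against 0.12 simulated, and probe sets are not independent replicates. This simulation gave each probe set the same spread in all groups. With the 4 spaceflight arrays split 2 and 2 between the comparisons, 86 to 973 probe sets were shared in the same direction and the covariance was 0.19 to 0.40. The balance turned with median centring, to 1008 higher and 1333 lower, and with the ratio covariate, to 104 higher and 136 lower, and quantile normalization gave 1223 higher and 743 lower. The shared count was 240 with the ratio covariate, 1 with the rRNA covariate, 485 with no filter, 989 by at least 2-fold, 3156 with the upper 40% filter, 930 without spaceflight replicates 1 and 2 and 3159 without replicates 3 and 4. It was 955 and 1301 without spaceflight replicates 1 and 2 in turn, and 775, 1019 and 426 without ground 1g replicates 1, 2 and 3 in turn.

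RAB21 fell from 12.78 ± 1.02 (SD, n = 3) in ground 1g to 7.93 ± 1.39 (SD, n = 3) in inflight 1g, a change of -4.85 (SE 0.76, limma adjusted p = 0.0197), and LTP-2 fell by 4.04 (SE 0.83). The auxin synthesis gene YUCCA1 fell by 3.85 (SE 0.33) and the auxin carrier gene PIN2 fell by 2.94 (SE 0.64). The floral regulator MADS58 fell by 3.16 (SE 0.45) and RFL fell by 3.12 (SE 0.45), the latter to a dim mean of 2.12. The copper transporter gene COPT3 fell by 3.05 (SE 0.40) and the proline synthesis gene P5CS2 fell by 3.02 (SE 0.48), to a dim mean of 4.06.

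The cytokinin oxidase gene CKX4 rose by 3.04 (SE 0.49) in inflight 1g, and TAC1, which controls tiller angle, by 3.01 (SE 0.59). HAK1 rose by 2.57 (SE 0.27), the cell cycle inhibitor gene KRP6 by 2.21 (SE 0.34), GLU6 by 2.14 (SE 0.42), OsGT47D by 2.09 (SE 0.34) and HSFA4D by 2.08 (SE 0.44). AOS1, of jasmonate synthesis, rose by 2.11 (SE 0.31).

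Of the planned lists, 3 were shifted between inflight 1g and ground 1g, and 0 with the 3' to 5' ratio or the rRNA signal as a covariate, no filter, only these groups in the fit or array weights, or without spaceflight replicate 4, spaceflight replicates 3 and 4 or ground 1g replicate 2. Of 25 settings the abscisic acid list was kept in 16 and the terpene and jasmonate lists in 10 each. The terpene and jasmonate lists were also lost with the upper 40% filter, median centring, and without inflight 1g replicate 1 or 3 or ground 1g replicate 1, the jasmonate list with quantile normalization and the terpene list without spaceflight replicate 3. Abscisic acid and dehydration genes were lower (camera adjusted p = 0.045, and adjusted p = 0.563 with an estimated correlation), with 3 of 5 lower, and 4 lower adjusted over the list alone, and RAB16B fell by 2.59 (SE 0.40). Genes of terpenes and cytochromes P450 were higher (adjusted p = 0.045, and adjusted p = 0.531 with an estimated correlation), with 4 of 24 higher, and 7 higher adjusted over the list alone. Its members AOS1 and EUI1 act in jasmonate synthesis and gibberellin breakdown, and EUI1 rose by 1.42 (SE 0.30) from a dim ground mean of 3.13. Jasmonate genes were higher (adjusted p = 0.045, and adjusted p = 0.583 with an estimated correlation), with 2 of 16 higher, and 5 higher adjusted over the list alone. The repressor genes JAZ3 and JAZ4 rose by 1.09 (SE 0.22) and 0.70 (SE 0.16), and the direction of this list turned with the 3' to 5' ratio as a covariate.

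Of 47 calcium signalling genes 3 were higher in inflight 1g, and 7 higher and 2 lower adjusted over the list alone. CIPK21 and CIPK2 rose by 1.87 (SE 0.32) and 1.11 (SE 0.20). Of 52 auxin response genes 2 were higher and 3 lower, and 5 higher and 12 lower adjusted over the list alone. GH3.6 and ARF16 rose by 0.95 (SE 0.17) and 0.81 (SE 0.17), while ARF22 fell by 0.94 (SE 0.14) and ARF24 fell by 0.99 (SE 0.17). Among symbol lists, cyclins and replication genes were lower (adjusted p = 0.000593, and adjusted p = 0.809 with an estimated correlation), with 4 of 65 lower, and 18 lower adjusted over the list alone, and CYCD4-2 fell by 2.62 (SE 0.21). Ribosomal proteins were lower as a list (adjusted p = 0.000727, and adjusted p = 0.809 with an estimated correlation), with 0 of 25 past the threshold over all genes and 10 lower adjusted over the list alone. Diterpenoid phytoalexin genes were higher (adjusted p = 0.00167, and adjusted p = 0.809 with an estimated correlation), with 1 of 11 higher, CYP71Z7 at 0.99 (SE 0.23), and 6 higher adjusted over the list alone. With the 3' to 5' ratio as a covariate 0 of these symbol lists were shifted.

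Between inflight 1g and ground 1g 1367 probe sets differed (limma with Benjamini-Hochberg adjustment), 518 higher and 849 lower, and 953 by at least 2-fold. The groups did not overlap for 33.7% of probe sets, where chance gives 10%. The share of higher calls was 37.9% as deposited, 60.7% after median centring, 47.2% after quantile normalization and 52.1% without ground 1g replicate 3. The count was 158 with no filter and 2790 with the upper 40% of probe sets, 2713 with the trend and robust model, 2678 with array weights and 421 with the rRNA covariate. Without spaceflight replicates 1 and 2 it was 2138, and 2232 without replicates 3 and 4. It was 844 and 805 without spaceflight replicates 1 and 3 in turn, 242 and 583 without inflight 1g replicates 1 and 2, and 208, 70 and 96 without ground 1g replicates 1, 2 and 3.

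Both flight groups differed from ground 1g in the same direction at 462 probe sets, 122 higher and 340 lower, and in opposite directions at 45. Independent lists would share 36.3 higher and 44.7 lower, and simulated unchanged groups sharing the ground arrays made 0 calls, so they gave no value for this overlap. The differences correlated across probe sets at r = 0.31 against 0.53 simulated, and 61.4% had the same sign against 67.8% simulated, both below the simulated value. The simulation gave each probe set the same spread in all groups and held no real differences. A value below it therefore does not show less sharing than chance. The covariance of the differences was 0.21 against 0.16 simulated. With the ground arrays split 1 and 2 between the comparisons, a check chosen after the data were seen, no array was shared and the covariance was 0.04 to 0.14, with r from 0.05 to 0.18. A lone ground array was then assumed to vary like the other groups, and 0 to 6 probe sets were shared in the same direction. Median centring gave 165 higher and 250 lower, and without ground 1g replicate 3 there were 19 higher and 17 lower. The shared count was 45 with no filter, 225 by at least 2-fold, 1026 with the upper 40% filter, 956 with the trend and robust model, 917 with array weights, 219 with the ratio covariate and 1 with the rRNA covariate. It was 249 and 250 without spaceflight replicates 1 and 3 in turn, 111 and 218 without inflight 1g replicates 1 and 2, and 75, 47 and 36 without ground 1g replicates 1, 2 and 3.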

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

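The tests of the BioB split and of RNA quality were chosen after the control probe sets had been seen and before any gene was tested, and the test of the rRNA controls after the gene results had been seen. The spike-in controls, used in no comparison, were brighter in the flight groups than in ground 1g. BioB was higher by 2.21 in spaceflight and 0.55 in inflight 1g on the log2 scale, BioC by 0.55 and 0.54, BioD by 0.39 and 0.47, and Cre by 0.33 and 0.42. The controls added to the RNA before labelling were higher by 1.48 and 0.73 for Dap, 1.47 and 0.67 for Lys, 1.54 and 0.78 for Phe, and 1.46 and 0.85 for Thr. Of 115 sets of 4 spaceflight values tested for an array far from the others, where chance gives about 1 in 20, ARD1 (LOC4348646) had a gap of 0.902 of its range, with spaceflight replicate 4 low, and JAZ3 (LOC4345625) a gap of 0.914, with spaceflight replicate 2 low.

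The difference between spaceflight and inflight 1g was 5999 probe sets, and other splits of these 7 arrays gave at most 2. The share of splits as large, 1 of 35, is under 0.05 and the smallest that 35 splits allow, so it argues against chance without excluding it. Separate hybridisation of spaceflight replicates 1 and 2 is argued against as the whole cause, since 2558 probe sets differed without them. With these replicates as the only spaceflight arrays the count was 7341. Dap, added before labelling, was 13.59 and 13.58 in them and 12.76 and 12.93 in replicates 3 and 4. Lys, Phe and Thr were brighter in them as well, while BioC, BioD and Cre did not split this way. The step at which these replicates came to differ is therefore unknown. RNA quality as read from the 3' to 5' ratio and RNA composition as read from the rRNA controls are also argued against as the whole cause, since 6935 and 4237 differed with these as a covariate. Gravity and any other difference between the flight groups, such as the centrifuge itself, stay open and untested.

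The difference between spaceflight and ground 1g was 4211 probe sets, with at most 2 in other splits. The share as large, 1 of 35, was again the smallest possible and argues against chance without excluding it. Without spaceflight replicates 1 and 2 the count was 2586, which argues against their hybridisation as the whole cause, and without replicates 3 and 4 it was 4649. RNA quality and RNA composition cannot be told apart from the groups here, because every ground array had a lower 3' to 5' ratio and a higher rRNA signal than every spaceflight array. With these as a covariate 431 and 1 probe sets differed, and the latter met the bound set beforehand for RNA composition as the cause. That bound did not foresee that the median size would change little, and it was set aside after the result was seen. The median size went from 0.98 to 0.89 and 0.93 and the median SE from 0.20 to 0.35 and 0.32. The size with the covariate over the size without it had a lower quartile of 0.63 and 0.72. Wider errors therefore had a part in ending the calls, with smaller sizes for some probe sets. Dap, added before labelling, also parted these groups, at 12.76 to 13.59 in spaceflight and 11.52 to 11.86 in ground 1g. Lys, Phe and Thr did so as well, and no fit took these controls as a covariate. Whatever made them differ was not tested and cannot be told apart from the groups either. Flight and gravity stay open as biological differences.

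Spaceflight replicates 1 and 2 differed from replicates 3 and 4, and this difference correlated at r = -0.22 across probe sets with inflight 1g minus ground 1g, which shares no array with it. A single axis along which both differences run the same way predicted a correlation above 0.2, and this was not met. The order of subtraction within spaceflight was arbitrary, and the reverse order turns the sign. The test therefore cannot decide whether both differences lie on a single axis. No biological explanation of the split was tested. Over the kept probe sets spaceflight replicates 1 and 2 correlated at 0.948 and replicates 3 and 4 at 0.947. The other spaceflight pairs correlated at 0.911 to 0.924. Spaceflight replicate 4 correlated at 0.920 and 0.917 with inflight 1g replicates 2 and 3, and at 0.884 with inflight 1g replicate 1. The fits and SDs took the 4 spaceflight arrays as independent. If the arrays came in pairs, the SEs and p-values may be too small.

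For inflight 1g against ground 1g, 1367 probe sets differed against at most 2 in other splits, with 1 of 10 as large, and 10 splits are too few for a share under 0.05. The 2068 probe sets shared by both spaceflight comparisons and the 462 shared by both flight groups stood against at most 1 and 3 in 100 random groupings, with 1 of 100 as large in each case. The other groupings called at most 14 probe sets in any comparison, which fixed their overlap near 0, so this test was void. Chance could not be excluded for the number of shifted lists. For spaceflight against inflight 1g, 15 of 35 splits gave as many planned lists (2 against at most 4) and 18 of 35 as many symbol lists (2 against at most 11). For spaceflight against ground 1g these were 3 of 35 (3 against at most 4) and 8 of 35 (4 against at most 8). For inflight 1g against ground 1g, 4 of 10 splits gave as many planned lists (3 against at most 8) and 4 of 10 as many symbol lists (3 against at most 10), with too few splits for a share under 0.05.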

How the results depend on the processing

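The covariate fit and the fits without a pair of spaceflight arrays were chosen after seeing the control probe sets, the rRNA covariate fit after seeing the gene results, and the symbol lists after seeing gene names. Among probe sets called both as deposited and in an alternative, 0 changed direction. Of the 135 named differences 0 reversed, and the threshold was lost by 76 with the replicate block, 72 with the rRNA covariate, 69 with the ratio covariate, 62 with no filter and at most 61 with any other setting. The upper 40% filter kept 117 of them, and the others had no value there. The cause of the shifts below was not tested, except that a stricter threshold can only lower a count. Leaving out arrays lowered some counts and raised others. Counts are in the order spaceflight against inflight 1g, spaceflight against ground 1g, inflight 1g against ground 1g, shared by both spaceflight comparisons, and shared by both flight groups against ground. With no filter they were 2877, 1017, 158, 485 and 45. With a 2-fold threshold they were 3554, 2056, 953, 989 and 225, and without spaceflight replicates 1 and 2 2558, 2586, 2138, 930 and 623. The upper 40% filter gave 2790, 3156 and 1026 for the last 3, and without spaceflight replicates 3 and 4 inflight 1g against ground 1g gave 2232 and both spaceflight comparisons shared 3159. The trend and robust model gave 2713 for inflight 1g against ground 1g and 956 shared by both flight groups, and array weights 2678 and 917. With only the groups compared, spaceflight against inflight 1g gave 3203, and the shared counts are not defined. With the ratio covariate spaceflight against ground 1g gave 431, and the shared counts were 240 and 219. With the rRNA covariate the last 4 were 1, 421, 1 and 1. The planned setting without a pseudocount equals the values as deposited. Leaving out each array in turn gave ranges of 3080 to 5988, 697 to 4585, 70 to 1245, 426 to 1878 and 36 to 344.

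The replicate number as a block gave 3516, 783, 6, 495 and 4. Deviations of same-numbered arrays correlated between -0.10 and 0.09, and those of other pairs between -0.11 and 0.12. This gave no sign that the numbers pair the arrays, but so few arrays cannot exclude it.

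Planned lists shifted in spaceflight against inflight 1g numbered 2, and 1 with no filter, 4 with the upper 40% filter, 4 with the replicate block, 4 without spaceflight replicates 1 and 2, 0 without spaceflight replicates 3 and 4, 4 with the ratio covariate and 1 with the rRNA covariate. In spaceflight against ground 1g the 3 lists became 0 with either covariate. In inflight 1g against ground 1g the 3 became 0 with no filter, 1 with median centring, 0 with only the groups compared, 0 with array weights, 0 without spaceflight replicates 3 and 4 and 0 with either covariate. Symbol lists in spaceflight against inflight 1g numbered 2, and 1 with no filter, 1 with the upper 40% filter, 1 with median centring, 1 with array weights, 4 with the ratio covariate and 5 with the rRNA covariate, and the 3 in inflight 1g against ground 1g became 0 with the ratio covariate. With an estimated correlation every count of lists was 0. WRKY factors and protein phosphatases 2C had estimates of -0.0123 and 0.0008, below the preset 0.01. The loss of these 2 calls therefore did not come from a higher correlation. Leaving out each array gave 0 to 4, 2 to 3 and 0 to 6 planned lists and 1 to 6, 3 to 6 and in each case 3 symbol lists. Of the 17 shifted lists, jasmonate genes in inflight 1g alone turned, in 1 of 25 settings.

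The 3' to 5' ratio difference of 0.10 between spaceflight and inflight 1g became -0.0913 without spaceflight replicates 1 and 2 and -0.0099 with middle in place of 5' probe sets, and 0.29 without spaceflight replicates 3 and 4. The middle probe sets took the differences from ground 1g of 0.59 and 0.49 to 0.26 and 0.27. Leaving out each array gave 0.02 to 0.20, 0.51 to 0.66 and 0.39 to 0.54 for the 3 comparisons. Detection calls were not used here, so how far signal over background limits the dim probe sets is unknown.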

Other observations

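The genes in this part were chosen after their values were seen. Among 24 DNA repair genes in a list based on symbols, 7 were higher and 0 lower in spaceflight against inflight 1g, and 8 higher adjusted over the list alone, and the list missed the threshold (camera adjusted p = 0.0779). PARP3, a poly(ADP-ribose) polymerase gene, was higher by 3.93 (SE 0.44, limma adjusted p = 0.00301) and the photolyase gene PHR, of light-driven DNA repair, by 1.84 (SE 0.17, limma adjusted p = 0.00239). Against ground 1g the same genes were higher by 1.79 (limma adjusted p = 0.0356) and 1.55 (limma adjusted p = 0.00475).

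In the list of kinases and other abscisic acid genes, 7 of 22 were higher and 1 lower in spaceflight against inflight 1g, and the list missed the threshold (camera adjusted p = 0.0779). Its higher genes include LEA19, RAB16B and RAB21, which also belong to the planned abscisic acid list, and EM, named above, so it is no separate support. The kinase genes SAPK1 and SAPK3 were higher by 1.83 (SE 0.25) and 1.47 (SE 0.29), and ABA8OX1, which breaks down abscisic acid, was lower, at -1.69 (SE 0.34). Chitinases and defence proteins had 2 of 25 higher and 6 lower, and 3 higher and 8 lower adjusted over the list alone, and missed it (camera adjusted p = 0.0545). This list shares Cht5, NH1 and other genes with the planned pathogenesis list, so it is no separate support. Of the sucrose synthase genes, SUS1 and SUS2 were lower, at -2.76 (SE 0.61, limma adjusted p = 0.0187) and -1.50 (SE 0.22), and SUS4 was higher by 1.59 (SE 0.23).

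A hypothesis formed after the dehydration transcripts had been seen was that seed maturation genes shifted more widely. It predicted higher seed storage genes in spaceflight, but 0 of the 6 annotated storage genes passed the filter on dim probe sets, so the test was void and the hypothesis stays undecided. VP1, a regulator of seed maturation, differed by 0.00 (SE 0.32) between spaceflight and inflight 1g.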
